A study of Mus musculus with 2 samples.

How the data were processed

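Long-read RNA sequencing was measured in hippocampus (per the labels, its layer) of male B6CASTF1/J mice aged 14 days, the first-generation hybrid of the C57BL/6J and CAST/EiJ strains. The 2 libraries are biological replicates 1 and 2 of a single group. The sample-level labels name different animals for each, while the experiment-level description repeats those of replicate 1 for both, so the spread between the libraries may be technical. Per the labels, each was made from 3 males and started from 2 µg of RNA, with ERCC spike-in controls and SIRV spike-ins added. The ERCC reads were used here and the SIRV spike-ins were not.

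The deposited tables give, per the file headers and the values themselves, raw read counts per transcript model, without normalization and without a minimum number of reads. Other columns of the deposited tables give the number of exons and the length in bases of each model, and the deposited annotation files give exon start and end positions and other descriptors of each model on mm10. Per the text deposited beside them, the authors used the mm10 assembly and GENCODE release M21, and made the values from an alignment of each library with the ENCODE uniform long-read pipeline. The aligner, the transcript caller and their versions are not given in the sources used here. The attribute names in the deposited annotation are those that TALON writes. Each model carries a class: annotated transcript, incomplete splice match (part of an annotated transcript), new combination of annotated splice sites, new splice site, genomic, antisense or intergenic. The class marks each model's relation to GENCODE M21 only.

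Reads were summed per gene over all models assigned to known genes, and all 18311 gene identifiers with reads matched GENCODE M21. CPM is reads divided by the mouse reads of the library, ERCC reads left out, and multiplied by 1000000. Models outside the catalogue were matched between the libraries by gene and the exact chain of introns. Shares of reads have Wilson intervals at 95% confidence. A count of 0 was taken to allow up to 3 reads, which is 3.65 CPM in replicate 1 and 4.03 CPM in replicate 2. Intervals and floors cover counting error only, since reads are not independent molecules once amplified. Values are means ± SD over the 2 libraries (n = 2).

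With 1 group there is no contrast between conditions, so every test between the libraries compares these libraries, not conditions. Its p-value measures departure from counting error only and takes no account of the usual spread between replicate libraries. Genes with at least 20 reads over both libraries were compared by Fisher's exact test, two-sided, against all other mouse reads, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was also counted as at least 2-fold different on CPM. Log2 ratios are replicate 2 over replicate 1 after adding 0.5 reads to each count. Gene lists (cell types, neighbouring tissues, programmes and quality checks; 30 lists, of which 29 had reads) were compared in the same way on summed reads, adjusted over the lists. Each list's median log2 ratio of CPM + 1 was also ranked among 10000 random lists of the same size matched on mean expression. Of the listed symbols, Nov was matched through its synonym in RefSeq to Ccn3. Pearson's r and Spearman's rho were taken across genes with at least 10 reads over both libraries on log2(CPM + 1). The biological coefficient of variation came from edgeR 4.0.16 with TMM normalization and an intercept-only design. The share of the first gene in each of 8 pairs was compared with 50% by an exact binomial test, two-sided, adjusted over pairs and libraries.

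Isoforms were counted from annotated and new transcripts, incomplete ones left out. A transcript counted with at least 5 reads over both libraries and at least 10% of its gene's reads of those classes. Isoform shares were compared for genes with at least 20 such reads in each library, by Fisher's exact test for 2 transcripts and by a chi-square test with 10000 simulated tables of fixed margins for more. The inclusion of an internal exon is the reads of models that hold it over those reads plus the reads of models of the same gene with an intron that spans it. Incomplete matches were included, and genomic, antisense and intergenic models were not. Exons with at least 20 such reads in each library and a mean inclusion of 5% to 95% were called variable and compared by Fisher's exact test.

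The gene lists, the pairs, the tests and the first set of alternatives were chosen before the data were examined. So was the rule for the genes named: the 10 nuclear genes with the highest mean CPM, the 4 most abundant members of every list and up to 4 members with 0 reads, the 10 largest ratios in each direction among called genes with at least a 2-fold difference, and the 5 most abundant long non-coding RNA genes. It also took the annotated variable exons of 90 fixed genes with the most reads (at most 25), the 10 genes with the most reads of new transcripts with at least 5 reads in each library, and the 5 lowest p-values among genes called for isoform shares, of which there were none. Genes named outside the rule are said to be so. Some genes and pairs taken by these choices are not reported here.

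The tests were tested on simulated data. Reads were drawn from the pooled shares, with 100 genes changed by each amount. The gene test recovered 54.0% of 2-fold and 93.0% of 4-fold changes and called 5 unchanged genes. With a spread of 0.105 between the libraries added it recovered 54.0% and 95.0% and called 191 unchanged genes of 8887 tested. The isoform test, with 100 genes shifted by each amount, recovered 49.0% of shifts of 20 percentage points and 89.0% of shifts of 40, and called 3 unchanged genes. So many shifted genes make it easier for the smallest simulated p to pass, so this recovery does not describe a case where few genes differ. The exon test recovered 27.0% and 74.0% of the same shifts and called 2 unchanged exons. A simulated coefficient of variation of 0.105 was estimated as 0.110.

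The alternatives were TMM library sizes or DESeq2 1.42.0 size factors, other read minimums and pseudocounts, annotated transcripts only, incomplete transcripts included or left out, mitochondrial genes left out, each list without its most abundant member, models seen in both libraries, stricter limits on exons and transcripts, the deeper library thinned, and each library left out. Added after the data were seen were genes without overlap on the same strand, reads over the same exons whatever gene they were given to, and 1000000 simulated tables. Reads over the same exons were those of models with at least 50% of their length on the exons of a gene's main models. A main model held at least 10% of the gene's reads. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3. Alleles of the parent strains were not analysed here, since the tables give no reads per allele.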

Results

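The data are long-read RNA sequencing of the hippocampus of male mice aged 14 days from the B6CASTF1/J hybrid. The 2 libraries are biological replicates of a single group, so the comparisons describe what the tissue expresses and how far its replicates differ. Replicate 1 held 832263 reads and replicate 2 held 753385 reads, of which 821324 and 743862 belonged to mouse transcript models and the others to ERCC spike-in controls, which are synthetic RNAs of known sequence. The ERCC share of all reads was 1.29% ± 0.0356 (SD, n = 2). At least 1 read was found for 16574 genes in replicate 1 and 16351 genes in replicate 2. Once replicate 1 was thinned to the 743862 mouse reads of replicate 2, it detected 16311 genes. Reads were found in both libraries for 14614 genes and in either for 18311. The median transcript model length per read was 2231 ± 29.7 bases (SD, n = 2), and 79.4% ± 1.28 of reads were spliced.

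Annotated transcripts held most of the reads, at 65.0% in replicate 1 (Wilson 95% interval 64.9% to 65.1%) and 63.5% in replicate 2 (63.3% to 63.6%), a mean of 64.2% ± 1.10 (SD, n = 2). Incomplete matches to an annotated transcript held 9.65% ± 0.0192 of reads. New combinations of annotated splice sites held 6.08% ± 0.0723, and transcripts with a new splice site held 3.84% ± 0.0162. Genomic models, of which 98.0% of reads had a single exon, held 6.73% ± 0.710 (SD, n = 2). Models antisense to a known gene held 8.39% ± 0.265, and models outside known genes held 1.09% ± 0.195. Models with 1 read made up 62.1% ± 0.355 of all models (SD, n = 2). Of 23989 annotated transcripts seen, 16045 were seen in both libraries and held 98.9% of that class's reads. Of 34976 structures with a new splice site, 3594 (10.3%) were seen in both libraries, and these held 43.5% of the class's reads.

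**Figure D1:**
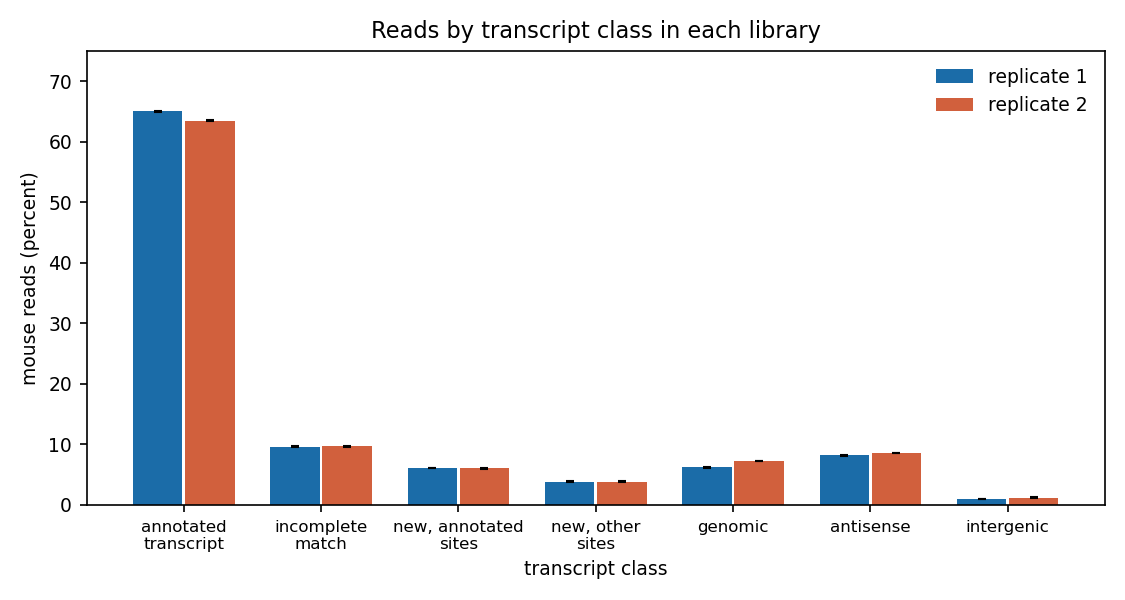
Percent of mouse reads in each transcript class (y axis) for the 7 classes (x axis), with 1 bar per library and Wilson 95% intervals as error bars. Annotated transcripts hold 65.0% and 63.5% of reads, and antisense models hold 8.20% and 8.57%.

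Apoe, the lipid carrier made mainly by astrocytes in brain, was the most abundant gene, at 6689 ± 255 CPM (SD, n = 2; mm10 chromosome 7, 19696109 to 19699188). The tubulins Tuba1a (6576 ± 196) and Tubb2a (5633 ± 192) came next, followed by Cpe (5346 ± 460), a carboxypeptidase that processes neuropeptides. Ubb, which encodes polyubiquitin, reached 3873 ± 148 CPM, and Mbp, which encodes myelin basic protein, reached 2717 ± 1456 CPM (SD, n = 2). The calmodulin gene Calm2 (2678 ± 62.7), the neuronal gene Ncdn (2582 ± 38.9) and the glycolytic gene Aldoa (2412 ± 428) were also among the 10 most abundant nuclear genes. Of those 10, Cpe, Mbp and Aldoa were called lower in replicate 2 (adjusted Fisher p 7.37e-06, 2.87e-133 and 8.45e-12). Among long non-coding genes, 2900097C17Rik had 455 ± 2.93 CPM, the imprinted Meg3 had 399 ± 59.8, and Gm44151 had 121 ± 1.49 (SD, n = 2). Cct6a, whose gene type in the annotation is processed transcript, had 338 ± 10.7 CPM. Gm48091 had 214 CPM in replicate 1 and 355 in replicate 2 and was called higher in replicate 2 (log2 ratio 0.73, adjusted Fisher p 4.02e-05). Gapdh had 20 and 9 reads, while its processed pseudogene Gm15459 had 1550 and 1420. Both were singled out after their values were seen, and reads shared between near-identical copies limit the value of either.

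Protein-coding genes held 97.7% ± 0.0679 of the reads of known genes (SD, n = 2), and processed pseudogenes held 0.874% ± 0.0512. Across 10969 genes with at least 10 reads, log2(CPM + 1) correlated between the libraries with a Pearson r of 0.943 and a Spearman rho of 0.940. Genes are not independent replicates, so no p is given. For 26 ERCC controls with at least 10 reads the r was 0.984. The biological coefficient of variation by edgeR was 0.105. A chi-square of 16269 on 8875 degrees of freedom, 1.83 per degree, shows that the counts differ by more than sampling noise, which separately prepared libraries of the same RNA can also do.

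Klhl10, Gm49450, Pcdhga2, BC065397 and Tcte1 had the largest ratios between the libraries. Klhl10 (mm10 chromosome 11) had 2 reads in replicate 1 and 244 in replicate 2, and Gm49450 had 5 and 212, log2 ratios of 6.75 and 5.41. Pcdhga2, a gamma protocadherin, had 51 reads in replicate 1 and 0 in replicate 2, BC065397 had 170 and 2, and Tcte1 had 124 and 2. Of 8875 genes tested, 140 were called: 66 higher in replicate 2 and 74 lower, while 911 had an unadjusted Fisher p under 0.05. Of these, 47 differed by at least 2-fold, 17 higher and 30 lower. With annotated transcripts alone, 74 of 6509 genes tested were called, 17 of them at least 2-fold, 4 higher and 13 lower. Simulated libraries with no change and the same spread of 0.105 gave 207 calls, 28 of them at least 2-fold. That spread was estimated from these same libraries, so it already holds the differences being counted. The number of called genes therefore cannot be judged against it. The number with at least a 2-fold difference was larger than in this single simulation.

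Emx2, a transcription factor of the developing cortex and hippocampus, had 11 reads in replicate 1 and 36 in replicate 2 (log2 ratio 1.81, adjusted Fisher p 0.00750). Cntnap2, a neurexin family member at the axon, had 17 and 41 (1.39, p 0.0395), and the potassium channel gene Kcnf1 had 8 and 28 (1.89, p 0.0279). Slc2a13, Zcchc8, Limd1, Coq3 and Gtf2a2 were also higher in replicate 2, with log2 ratios from 1.57 to 2.02. On annotated transcripts alone Slc2a13, Coq3 and Gtf2a2 no longer passed, at log2 ratios of 2.22, 0.86 and 1.46 against 2.02, 1.65 and 1.57, nor did Gtf2a2 with TMM library sizes, at 1.55. Only 4 others of the 20 genes with the largest ratios had a value on annotated transcripts alone, and they kept their call. The rest could not be compared in that setting. On the lower side, Ccdc159 had 92 and 6 reads (log2 ratio -3.69), Gm37313 had 44 and 4, Gm49325 had 20 and 1, and AC140073.1 had 20 and 3. The pseudogenes Mpc1-ps (62 and 5), Cbx3-ps6 (56 and 8) and Gm11223 (32 and 2) were also lower in replicate 2. Reads over the same exons and strand, whatever gene they had been assigned to, were 169 and 243 for Klhl10, 109 and 93 for Pcdhga2, 122 and 138 for Tcte1 and 326 and 316 for Ccdc159. For these 4 genes the reads over the same exons differed by 1.06-fold to 1.59-fold. Of the 20 genes with the largest ratios, 13 differed in the same direction by at least 2-fold on reads over the same exons, among them Gm49450 (0 and 210), BC065397 (306 and 130), Gm11223, Mpc1-ps, Cbx3-ps6, Zcchc8, Kcnf1 and Emx2, and 7 did not.

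**Figure D2:**
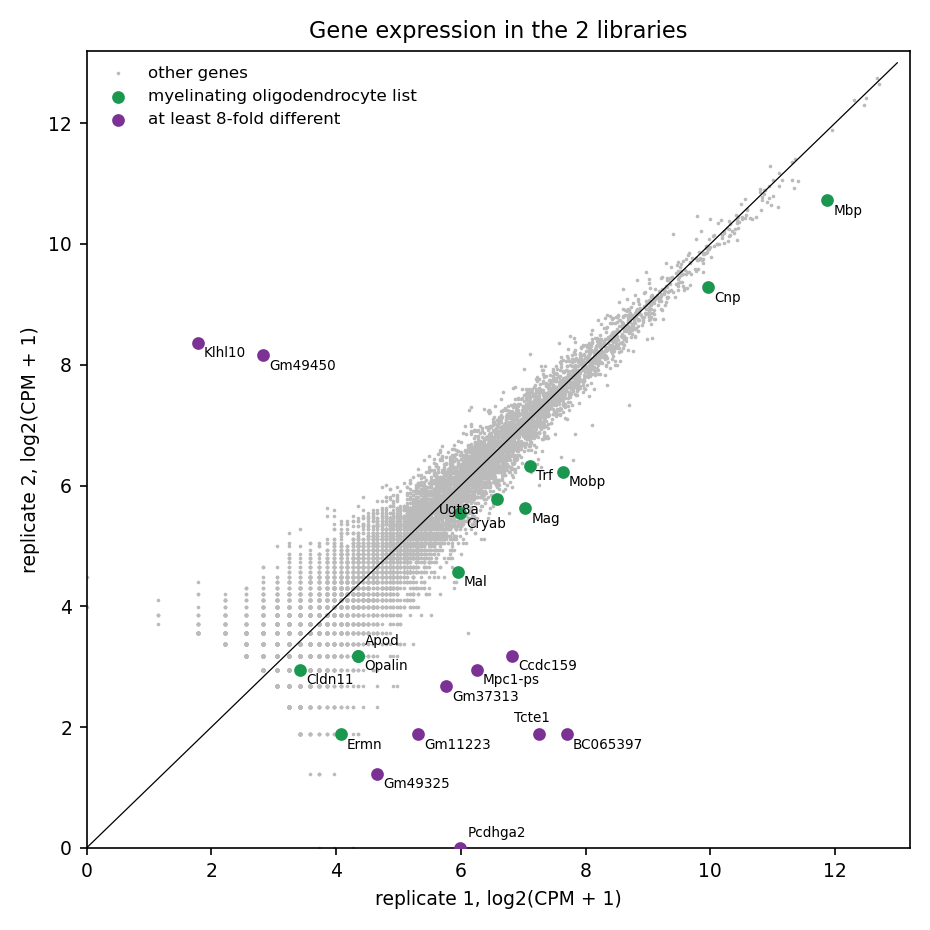
Expression of each gene with at least 10 reads over both libraries, as log2(CPM + 1) in replicate 1 (x axis) and replicate 2 (y axis), with 1 point per gene. Of the myelinating oligodendrocyte list, 12 genes (green) lie below the line of equal values, and 10 genes differ by at least 8-fold (purple).

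Myelin genes were lower in replicate 2. Mbp (mm10 chromosome 18, 82475146 to 82585637) had 3746 CPM in replicate 1 and 1687 in replicate 2, a log2 ratio of -1.15. Cnp, a phosphodiesterase of myelin, had 812 ± 269 CPM (SD, n = 2; log2 ratio -0.69), and Mobp had 136 ± 87.2 (-1.41). The list of 15 myelinating oligodendrocyte genes summed to 5037 reads in replicate 1 and 2294 in replicate 2, a log2 ratio of -0.99 (adjusted Fisher p 8.30e-175), and all 15 members had a lower CPM in replicate 2. Of 11 members tested, 7 were called lower, 0 higher and 4 did not pass; adjusted over the list alone, 8 were called lower. The list's median log2 ratio was below that of all 10000 random lists matched on expression. Without Mbp the list's log2 ratio was -0.77, and the call held. The oligodendrocyte precursor list had 635 and 514 reads (log2 ratio -0.16, adjusted p 0.106 by Fisher's test), with Olig1 at 223 ± 43.1, Olig2 at 119 ± 3.39, Bcas1 at 68.0 ± 27.8 and C1ql1 at 61.6 ± 7.93 CPM (SD, n = 2). It passed on annotated transcripts alone, at -0.30, and on reads over the same exons, at -0.22.

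Of the 8 lists of neurons and dividing cells, 3 were higher in replicate 2, 1 was lower and the others did not pass. No test compared their ratios with that of the myelin list. Ccn3, a marker of CA1 pyramidal neurons, had 389 ± 93.2 CPM (SD, n = 2) and was called higher in replicate 2 (log2 ratio 0.49, adjusted Fisher p 0.00439). The CA1 list, with Wfs1 (171 ± 22.8), Pou3f1 (164 ± 1.21) and Mpped1 (144 ± 11.0), had 758 and 863 reads, a log2 ratio of 0.33 (adjusted Fisher p 4.44e-05). The dentate granule list had 190 and 248 reads (log2 ratio 0.53, p 7.33e-04), led by C1ql2 at 129 ± 28.9 CPM, and no member was called. The CA2 list had 642 and 468 reads (-0.31, Fisher p 0.00111), with Necab2 called lower and Pcp4 at 247 ± 1.67 CPM. The CA3 list, with Bok at 182 ± 42.4 and Nectin3 at 83.0 ± 1.42 CPM, did not pass (312 and 246 reads, p 0.174 by Fisher's test). The GABAergic list had 777 and 843 reads (log2 ratio 0.26, p 0.00111), with Cck at 437 ± 68.5, Gad1 at 221 ± 37.2, Calb2 at 163 ± 3.02 and Sst at 50.3 ± 14.4 CPM (SD, n = 2). The glutamatergic list did not pass (2673 and 2500 reads, Fisher p 0.335), with Nrgn at 1606 ± 148 and the vesicular glutamate transporter Slc17a7 at 1282 ± 90.1 CPM. The immature neuron list did not pass either (1473 and 1352 reads, Fisher p 0.819), with Stmn2 at 697 ± 48.8 and Tubb3 at 683 ± 22.5 CPM. Over the 8 lists of neurons and dividing cells, 1 member was called higher in replicate 2 and 1 lower of 46 tested; adjusted over the list alone, 4 were called higher and 2 lower. The CA2 and GABAergic lists no longer passed without Necab2 and Cck, at log2 ratios of -0.19 and 0.22, or on annotated transcripts alone, at -0.18 and 0.11.

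Of the astrocyte, microglia, vascular and cell division lists, only the microglia list passed with all members and all reads of known genes counted. The astrocyte list had 12852 and 11403 reads (log2 ratio -0.03, adjusted Fisher p 0.174), with Sparcl1 at 1850 ± 159 and Ndrg2 at 1205 ± 93.7 CPM (SD, n = 2). Its member Aldoc, the brain aldolase, was called lower in replicate 2 (log2 ratio -0.30, adjusted Fisher p 7.35e-05), and adjusted over the list alone 2 members were called higher and 4 lower of 16. The astrocyte list passed without Apoe (-0.11), on annotated transcripts alone (-0.08) and with TMM library sizes (-0.04). The microglia list had 1023 and 830 reads (-0.16, Fisher p 0.0418) and its median log2 ratio was 0.10, of the opposite sign. Its most abundant member was Sparc (493 ± 84.8), and without it the list's log2 ratio was -0.02 and the list did not pass. The vascular list, with the tight junction gene Cldn5 at 345 ± 32.8 CPM (SD, n = 2), had 710 and 578 reads (p 0.106 by Fisher's test). The cell division list had 35 and 42 reads (Fisher p 0.335), with Rrm2 at 13.5 ± 1.85 CPM and Hist1h1b at 0 reads in both libraries.

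Among markers of neighbouring tissue, Ttr, the thyroid hormone carrier made by choroid plexus, had 194 CPM in replicate 1 and 87.4 in replicate 2 (log2 ratio -1.14, adjusted Fisher p 6.30e-06). The choroid plexus and ependyma list had 179 and 81 reads (log2 ratio -0.996, adjusted Fisher p 1.47e-06). That call rested on Ttr, since the ratio of the other members was -0.17 and did not pass. Prlr and Aqp1 of that list had 0 reads. Blood transcripts were present in both libraries, with Hba-a1 at 163 ± 22.3 and Hbb-bs at 83.9 ± 12.2 CPM (SD, n = 2), and Slc4a1 at 0 reads. The blood list (270 and 230 reads, Fisher p 0.607), the meninges and fibroblast list (198 and 199, p 0.397, with Col3a1 at 95.8 ± 16.6 CPM) and the thalamus and habenula list (254 and 198, p 0.183, with Prkcd at 54.0 ± 9.78) did not pass. Nor did the neocortex list (117 and 126 reads, Fisher p 0.258, with Mef2c at 40.95 ± 20.03) and the striatum list (77 and 66, p 0.861, with Ppp1r1b at 35.1 ± 19.2). The blood list passed without Hba-a1, at -0.47. The summed and median log2 ratios of the neocortex and striatum lists had opposite signs. Pou4f1, Rorb and Adora2a had 0 reads in both libraries. Over these 6 lists, only Ttr was called of 21 members tested; adjusted over the list alone, 1 neocortex member was higher and Ttr and 1 striatum member were lower.

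Arc, which acts at active synapses, was lower in replicate 2, with 67 and 25 reads (57.6 ± 33.9 CPM, SD, n = 2; log2 ratio -1.26, adjusted Fisher p 0.0106), and Dusp1, named after its values were seen, had 37 and 10 (-1.69, p 0.0297). The activity-regulated list had 529 and 405 reads (log2 ratio -0.24, Fisher p 0.0305), with 2 of 11 tested members called lower and 9 not passing; adjusted over the list alone the count was also 2. Its median log2 ratio, -0.57, was below that of all 10000 random lists, and 9 of its 12 detected members had a lower CPM. The list did not pass without Junb or on annotated transcripts alone, at -0.24 and -0.14. Junb had 137 ± 16.6, Homer1 104 ± 27.2 and Nptx2 66.6 ± 4.66 CPM, and Npas4 and Fosb had 0 reads. The synaptic vesicle list had 7883 and 6637 reads (log2 ratio -0.11, Fisher p 7.86e-05), with Syp (1486 ± 147) and Snap25 (1223 ± 211) called lower, and Rab3a (984 ± 14.7) and Vamp2 (980 ± 27.2) not; 2 of 16 were also called adjusted over the list alone. The median log2 ratio of that list, -0.05, lay at percentile 27.1 of the random lists, within their range. List sums leave antisense reads out, and the vesicle gene Cplx2 had 851 and 1781 of them against 235 and 218 sense reads. The direction of the vesicle list therefore holds for sense reads only. The postsynaptic density list had 4224 and 4163 reads (0.12, Fisher p 6.31e-04), with the phosphatase gene Ppp3ca at 1859 ± 107, Camk2b at 871 ± 30.3 and Baiap2 at 208 ± 15.5 CPM. None of its 14 tested members was called over all genes, and 1 was called higher adjusted over the list alone. Glutamate receptors had 1401 and 1385 reads (log2 ratio 0.13, Fisher p 0.0447), led by Gria2 (456 ± 5.69), Grin1 (440 ± 19.02), Gria1 (313 ± 30.9) and Grik5 (158 ± 11.98), with no member called of 15 and Grm8 at 0 reads. That list did not pass with TMM library sizes, at 0.11, or on annotated transcripts alone, at 0.05. GABA-A receptor and chloride transport genes had 796 and 723 reads (0.00, Fisher p 0.959), led by Gabra5 at 356 ± 19.5 CPM (SD, n = 2), and their median log2 ratio was -0.03.

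Imprinted genes were led by Snrpn (1661 ± 210 CPM, SD, n = 2), which was called lower in replicate 2 (log2 ratio -0.26, adjusted Fisher p 9.64e-04), Ndn (569 ± 18.0) and Nnat (541 ± 64.1). Their list had 2962 and 2443 reads (log2 ratio -0.13, Fisher p 0.00179; median -0.06 at percentile 28.6 of random lists) and did not pass without Snrpn, at -0.02. Adjusted over the list alone, 1 member was called higher and 2 lower of 9 tested. Snurf, Zim1 and H19 were assigned 0 reads. Reads over the same exons were not counted for genes with 0 reads, so assignment to an overlapping gene stays open. The chaperone genes Hspa8 (2214 ± 98.1) and Hsp90ab1 (1755 ± 79.5) led the stress list (4339 and 3722 reads, log2 ratio -0.08, Fisher p 0.0358; median -0.09 at percentile 20.01 of random lists), in which Atf3 had 0 reads. It did not pass without Hspa8, at -0.07 with fewer reads, or on annotated transcripts alone, at -0.04. Mitochondrially encoded mRNAs had 260 and 318 reads (0.43, Fisher p 0.00111), with mt-Co1 at 153 ± 16.1 CPM and mt-Nd4l and mt-Nd6 at 0 reads. Housekeeping genes had 3533 and 3183 reads (-0.01, Fisher p 0.865), with Actb at 1277 ± 5.37, Ppia at 892 ± 33.3, Ywhaz at 824 ± 55.0 and Pgk1 at 480 ± 53.2 CPM. The Y-linked list had 112 and 94 reads (Fisher p 0.726), with Ddx3y at 60.01 ± 1.22 and Eif2s3y at 54.6 ± 8.83 CPM, and Xist had 0 reads in both libraries. In all, 14 of 29 lists passed, 6 higher and 8 lower in replicate 2. Without the most abundant member 7 of these 14 still passed and 7 did not, while the astrocyte and blood lists, which had not passed, did. Fisher's test on summed reads allows for counting error only, and the lists were not simulated with the spread of 0.105 between the libraries. Small ratios on many reads may pass through that spread alone.

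**Figure D3:**
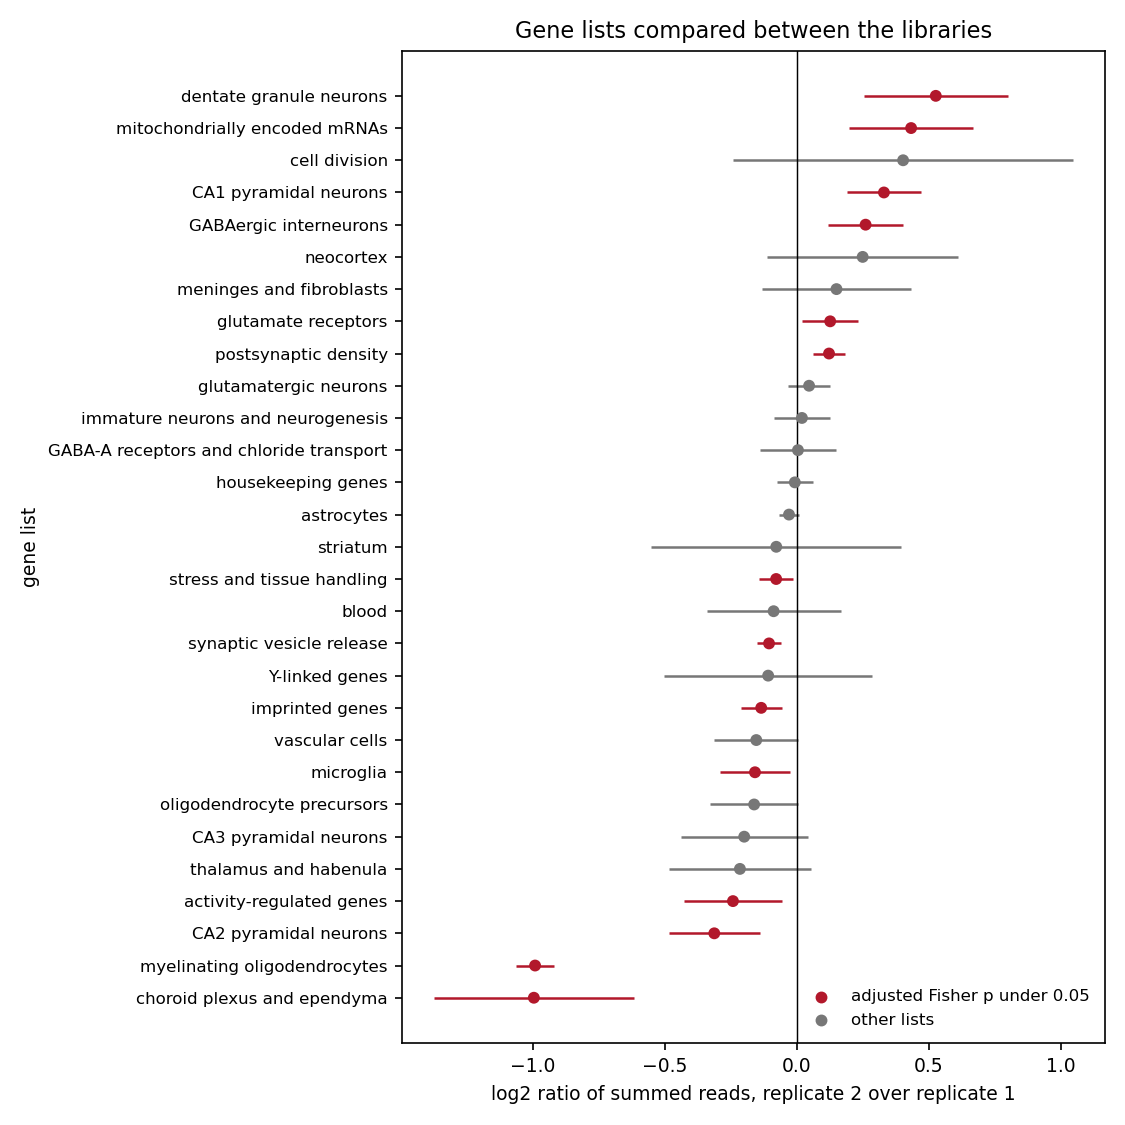
Log2 ratio of each list's summed reads, replicate 2 over replicate 1 (x axis), for the 29 lists with reads (y axis), with 95% intervals from counting error as lines. The myelinating oligodendrocyte list lies at -0.99 and the choroid plexus list at -0.996, and the dentate granule list lies highest, at 0.53.

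Grin2b, the NMDA receptor subunit that predominates early in life, held 69.9% ± 0.551 (SD, n = 2) of the reads of Grin2b and Grin2a. Slc12a5, the transporter that extrudes chloride from neurons, held 74.2% ± 1.18 of its reads with Slc12a2, which imports it. Dcx, a marker of immature neurons, held 2.61% ± 1.25 of its reads with Rbfox3, a marker of mature ones (SD, n = 2). That share rests on only 4 and 8 reads of Dcx, against 228 and 221 of Rbfox3. Gad1 held 87.7% ± 7.39 with Gad2, Slc17a7 held 98.96% ± 0.0750 with Slc17a6, and Hba-a1 held 65.9% ± 6.33 with Hbb-bs. All 6 of these pairs differed from 50% in the same direction in both libraries by the exact binomial test, with adjusted p from 0.00405 for Grin2b in replicate 1 downwards. The pair of Grin2b had 41 and 18 reads in replicate 1 and 52 and 22 in replicate 2 (Wilson 95% intervals 56.9% to 79.7% and 59.1% to 79.5%). The direction of the Slc12a5 pair depended on transcript class, since on annotated transcripts alone Slc12a5 held 5%. That share rests on few reads, 1 of Slc12a5 against 9 of Slc12a2 in replicate 1 and 0 against 8 in replicate 2. The Grin2b pair did not pass without incomplete transcripts, where Grin2b held 62.4%. On annotated transcripts alone it held 100% of only 2 reads, all in replicate 1, too few to pass. A bias of the assay with gene length, which was not tested for these pairs, limits what all these shares show.

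Snap25, Pkm and Mbp each divided their reads between annotated isoforms. The most abundant isoform of Snap25, of 2116 bases, held 81.4% ± 3.16 of the gene's counted reads, and the next held 16.3% ± 3.13 (SD, n = 2). In Pkm these shares were 80.3% ± 1.80 and 16.7% ± 1.48. Mbp used 3 isoforms, at 48.1% ± 2.37, 18.9% ± 1.03 and 16.6% ± 0.241 (SD, n = 2). Across 9949 genes with a counted transcript, 2665 (26.8%) had at least 2 that each held at least 10% of reads. Of these, 2131 had 2 transcripts, 441 had 3, 86 had 4 and 7 had 5. The count of 2665 was 1708 without replicate 1 and 1885 without replicate 2, 1686 with a minimum of 10 reads and 1481 with a limit of 20% of reads. Among 7508 genes with at least 20 such reads, the most abundant transcript held a median of 81.9%, and in 1249 genes (16.6%) it held less than 50%.

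Rhbdl1, a rhomboid family protease gene, had the lowest p for a difference in isoform shares, and was named after its values were seen. Its main annotated isoform held 60 of 60 reads in replicate 1 and 41 of 62 in replicate 2 (66.1%). Of 2601 genes tested by Fisher's exact test or simulated tables, 0 were called, and 146 had an unadjusted p under 0.05. With incomplete transcripts included, 184 of 3378 genes were called, and on annotated transcripts alone 1 of 1608 was, Ddx5. With 10000 simulated tables the smallest p that can be given is 1e-04, which would need 6 genes to reach it before any of them passed, and 2 did. With 1000000 simulated tables, an alternative added later, Rhbdl1 passed at the smallest p those can give, 1e-06 (adjusted p 0.00260).

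In 10 abundant genes, transcripts outside the catalogue were seen in both libraries. Nrgn, a calmodulin-binding protein of dendritic spines, had 94.3% ± 0.947 of its reads in such transcripts (SD, n = 2). Its main one, with 1165 and 1185 reads, had 3 exons and an intron at mm10 chromosome 9, 37545349 to 37545947, whose acceptor lay 17 bases from the nearest annotated one. The shares were 97.4% ± 0.494 and 95.9% ± 0.764 in the antizyme genes Oaz1 and Oaz2, whose main new transcripts were new combinations of annotated introns and held 95.2% ± 0.233 and 90.03% ± 0.0872 of reads. They were 89.5% ± 0.511 in Sept7 and 61.3% ± 0.358 in the kinesin light chain gene Klc1, whose main new transcripts joined annotated splice sites in a new intron and held 87.5% ± 0.932 and 21.5% ± 0.724 (SD, n = 2). Pitpna (89.0% ± 0.412) used a donor 4 bases from an annotated one, and Uchl1, a neuronal ubiquitin hydrolase, used a donor 9 bases away in 78.5% ± 4.55 of its reads (SD, n = 2). Hnrnpk (80.9% ± 0.315), Apbb1 (69.9% ± 1.40) and Ctbp1 (57.0% ± 0.109) completed the 10. In all, 1348 structures outside the catalogue in 1004 genes had at least 5 reads in each library.

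Snap25 chose between a pair of adjacent exons of 118 bases each. The upstream one (mm10 chromosome 2, 136769743 to 136769860) was included in 14.3% of reads in replicate 1 and 18.8% in replicate 2, and the downstream one (136770057 to 136770174) in 85.6% and 81.2%. Pkm, the muscle and brain pyruvate kinase, included the upstream 167-base exon that makes the M1 isoform in 81.9% ± 1.497 of reads and the downstream exon that makes M2 in 18.0% ± 1.23 (SD, n = 2). App included the 168-base exon that encodes the Kunitz protease inhibitor domain in 8.43% ± 0.163 of reads, while Aplp2 included its exon of the same length in 86.2% ± 1.13. Grin1 included its 111-base exon in the intracellular tail in 48.4% ± 4.06 of reads, and Gria2 used its 115-base alternatives in 57.3% ± 3.60 (start 80690404) and 44.6% ± 3.96 (start 80691320; SD, n = 2). Mbp included its 78-base exon in 25.9% ± 0.298, its 33-base exon in 93.3% ± 2.55 and its 123-base exon in 31.9% ± 1.68 of reads.

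No exon taken by the rule, including those of Snap25, Pkm, App and Mbp, differed between the libraries by Fisher's exact test adjusted over all variable exons. The calcineurin gene Ppp3ca included a 30-base exon in 72.9% ± 0.975 of reads, Ndrg4 a 39-base exon in 67.4% ± 2.97 and Ndrg2 a 42-base exon in 18.3% ± 1.44 (SD, n = 2). Camk2b included exons of 45 and 75 bases in 87.0% ± 1.24 and 92.7% ± 0.226. Cadm1, a synaptic adhesion gene, included exons of 84, 33 and 54 bases in 30.4% ± 6.03, 58.3% ± 0.264 and 13.7% ± 2.05 of reads. The tropomyosin gene Tpm3 used 1 of 2 exons of 76 bases, in 77.4% ± 0.614 (start 90089048) and 22.2% ± 0.775 (start 90088401), and a 79-base exon in 5.57% ± 0.438. A 36-base exon of Aplp2 was included in 73.8% ± 1.70 of reads, but in 22.9% without incomplete transcripts, and its 168-base exon in 59.5%. On annotated transcripts alone the 2 exons of Tpm3 exchanged places, at 26.5% and 73.5%.

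**Figure D4:**
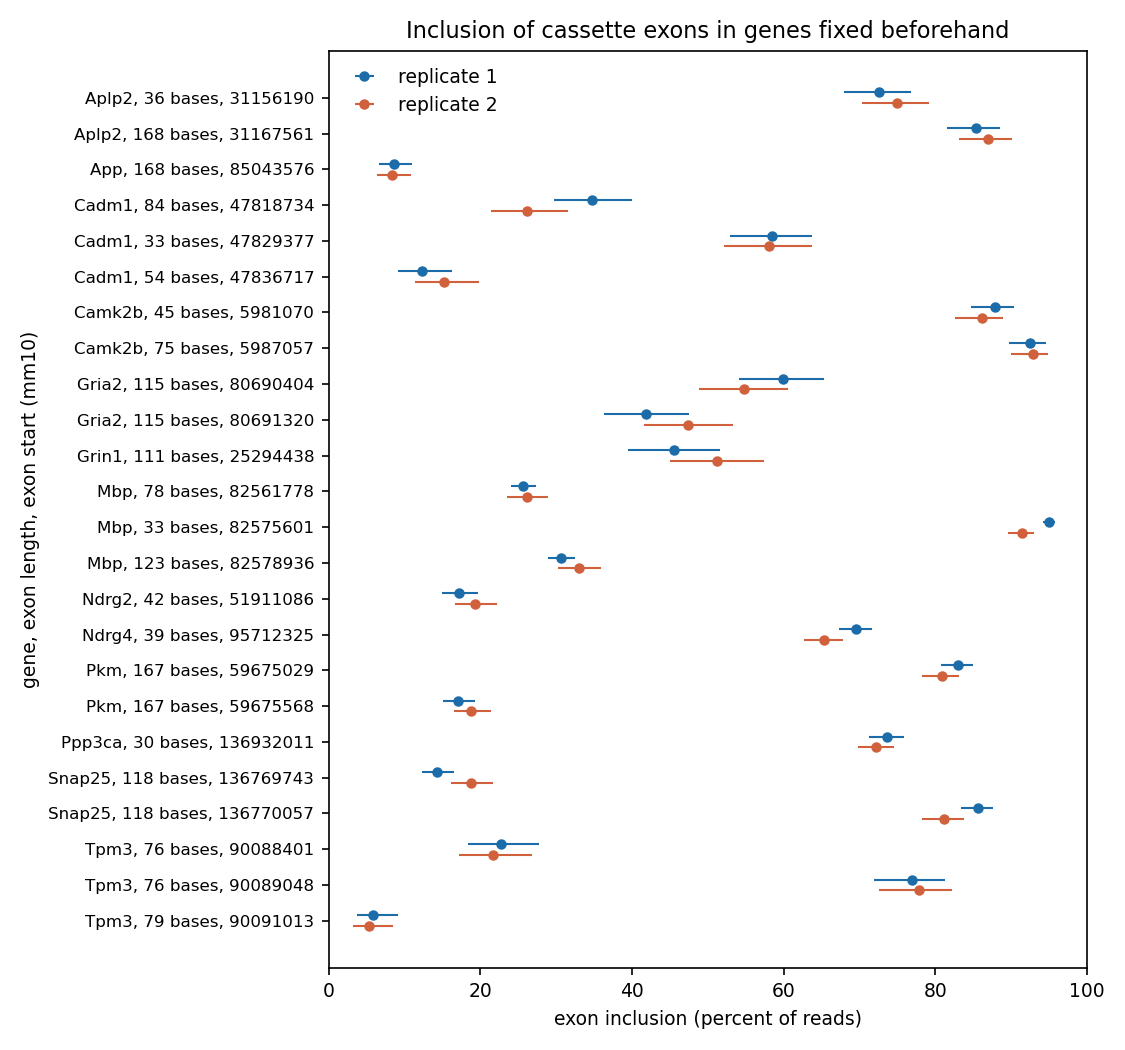
Inclusion of 24 annotated variable exons as a percent of reads (x axis) in replicate 1 (blue) and replicate 2 (red), with Wilson 95% intervals as lines; each line of the y axis gives the gene, the exon length and its start on mm10. The exon of App lies at 8.55% and 8.32%, and the 33-base exon of Mbp at 95.1% and 91.5%.

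Of 13124 exons tested, 2276 in 1339 genes were variable, of which 2097 were annotated and 179 were not. The number of variable exons was 586 with annotated transcripts alone, 841 with at least 50 reads in each library and 1387 at 10% to 90% inclusion. For the 2276, inclusion correlated between the libraries with a Pearson r of 0.971 and a Spearman rho of 0.905 across exons, which are not independent replicates. By Fisher's exact test 1 exon differed between the libraries, and 96 had an unadjusted p under 0.05. That exon, of 162 bases in Rhbdl1 (mm10 chromosome 17, 25836411 to 25836572), was named after its values were seen. It was included in 100% of 73 reads in replicate 1 (Wilson 95% interval 95.0008% to 100%) and in 81.1% of reads in replicate 2 (72.0% to 87.7%; adjusted Fisher p 0.0423). Without incomplete transcripts it was no longer called, at 100% and 83.6% (adjusted Fisher p 0.276), and 0 exons were. On annotated transcripts alone it was not among the exons called. The 33-base exon of Mbp did not pass over all variable exons (adjusted Fisher p 0.0609) and passed with at least 50 reads in each library (p 0.0225) and on annotated transcripts alone (p 0.0110). Among 1598 coding variable exons, 57.8% had a length that is a multiple of 3, which leaves the reading frame intact whether the exon is used or not. Among 7142 coding exons with some skipping reads and inclusion above 95%, 39.0% did (odds ratio 2.14, Fisher's exact test across exons, p 2.24e-42). Exons of the same gene are not independent, which this p does not allow for.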

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

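The tests of read orientation and of genomic DNA priming were chosen only after the results were seen.

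Reads antisense to known genes were found in data that no comparison used, above the limit that a count of 0 allows, and made up 8.39% ± 0.265 of mouse reads (SD, n = 2). By their class these 131122 reads lie opposite a known gene, and such a gene was found in GENCODE M21 for 99.6% of them. Single-exon models held 98.0% of the 131122 reads. In 210 genes the antisense reads outnumbered the sense reads in both libraries, with at least 20 antisense reads in each. Snhg11 had 1943 and 1175 antisense reads against 108 and 83 sense reads and Map1b had 730 and 737 against 32 and 32. Some loci differed between the libraries: Slc1a2, the astrocyte glutamate transporter, had 369 and 2499 antisense reads, and the synaptic scaffold gene Shank1 had 3 and 1242. These genes were chosen after their values were seen. Slc1a2 is in the astrocyte list and Shank1 in the postsynaptic density list, whose sums leave antisense reads out, so those comparisons hold for sense reads only. The locus with the most antisense reads was Gm26917 (mm10 chromosome 17, 39843013 to 39846341), at 5942 ± 2216 CPM (SD, n = 2). It had 6167 and 3254 antisense reads against 16 and 19 sense reads, and which RNA these came from was not tested. Models outside known genes, which no comparison used either, held 1.09% ± 0.195 of mouse reads (SD, n = 2). Among the ERCC controls, 4 had antisense reads only, 188 over both libraries (107 and 81), and 0 sense reads.

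Antisense reads in the wrong orientation would also appear on ERCC controls. Of the 20462 reads of all 55 controls, 0.919% were antisense (Wilson 95% interval 0.797% to 1.06%), below the 8.48% of reads at mouse genes. All of them lay on the 4 controls without sense reads, which are 7.27% of the controls (2.86% to 17.3%), so wrong orientation at some loci stays open. For 14849 single-exon models with 1 read, the 3' end lay in an exon of the opposite gene in 7.55%, against 11.3% of those gene bodies that is exon, a ratio of 0.668. Ends at annotated exon boundaries and ends outside the opposite gene had been left out. Leaving out ends at exon boundaries can lower this ratio. Priming of genomic DNA may explain the models with 1 read, although reads of unspliced RNA could give the same ratio. In the models with at least 20 reads, which hold 43.5% of the reads, 79.8% of bases lay in exons against 44.7% from the gene bodies, an odds ratio of 4.89. This test counted bases weighted by reads, not 3' ends, so it is unlike that of the models with 1 read. Each model was set against the opposite gene with the largest exon overlap, which raises the share in exons. Genomic DNA as a source of these models is therefore neither shown nor excluded.

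Where the end of such a model lay in an exon, the sense strand beside it was rich in T, so that the antisense strand was rich in A, where oligo-dT anneals. Of 1121 ends of models with 1 read, 70.9% had at least 12 T in the 20 adjacent bases, against 6.16% of random positions in the same exons, a ratio of 11.5. For models with at least 20 reads the ratio was 11.8. On simulated ends the same test gave 6.73 when part of the ends were placed at T-rich positions and 0.925 when none were. Internal priming may therefore explain antisense ends in exons, but the test does not tell which molecule was primed. Ends in introns, 92.5% of those of models with 1 read and 51.9% of those with at least 20, were not tested. No biological explanation was tested, and transcription of the antisense strand stays open.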

How the results depend on the processing

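The tests on genes without overlap, on reads over the same exons and with 1000000 simulated tables were chosen only after the results were seen. Over 399 values, 320 kept their direction and their side of the threshold, moved by less than the spread or, for counts, stayed within 1.5 times; of the 57 that answer a comparison, 35 did. In all, 11 changed direction. On annotated transcripts alone the share of Slc12a5 in its pair was 5%, from only 1 and 0 reads of Slc12a5 against 9 and 8 of Slc12a2. The others were lists that passed in neither setting: without their most abundant member the CA3 (0.0899), glutamatergic (-0.0868), neocortex (-0.0167), striatum (0.57) and GABA-A receptor (-0.0579) lists, on annotated transcripts alone the glutamatergic (-0.0853), GABA-A receptor (-0.0361), Y-linked (0.0451) and housekeeping (0.00615) lists, and with TMM library sizes the GABA-A receptor list (-0.0102). Where no cause is given, the cause was not tested.

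On annotated transcripts alone, 74 genes differed (66 of them among the 140), where 6509 genes were tested in place of 8875; 586 exons were variable, and 1 gene, Ddx5, was called for isoform shares. With incomplete transcripts included, 184 genes were called for isoform shares; Rhbdl1 was the 1 gene called with 1000000 simulated tables. Without incomplete transcripts, and at 10% to 90% inclusion, 0 exons differed; at 10% to 90% the exon of Rhbdl1, at a mean of 90.5%, is left out by construction. At 10% to 90%, 1387 exons were variable. With at least 50 reads in each library 841 exons were variable and 2 differed, in Rhbdl1 and Mbp. At least 2 transcripts were counted in 1481 genes at 20% of reads and in 1686 with 10 reads. These stricter limits leave fewer exons and transcripts. The number of genes with at least 2 transcripts was 1708 to 1885 with 1 library left out (1708 without replicate 1), and that of variable exons 2709 to 2742.

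The share of annotated transcripts was 68.9% in models with at least 2 reads and 74.0% in models seen in both libraries, and that of antisense reads 7.98% and 6.26%; both filters remove models with 1 read. The correlation was 0.939 with a pseudocount of 0.5, 0.932 with no minimum and 0.947 with 50 reads, and the coefficient of variation was 0.103 with 50 reads. Without their most abundant member 9 lists passed in place of 14: 7 of the 14 and 2 others, with 7 calls lost. With annotated transcripts alone 11 passed, 9 of the 14 and 2 others. Elsewhere the number of genes that differed was 114 to 140 and that of lists 13 to 15. Of the named exons, 22 of 25 had a value on annotated transcripts alone, of which 8 moved, and 22 without incomplete ones, of which 4 moved. No paired analysis was possible because there is 1 group. Depth limits the gene test, which recovered 54.0% of simulated 2-fold changes.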

Other observations

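The exon pairs and their tests were chosen only after the exon results were seen; the tests of read assignment and of transcript length were chosen before their results were seen.

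Long reads show which exons sit on the same molecule. The pair of 118-base exons of Snap25 was never on the same read, with 0 of 1079 reads in replicate 1 and 0 of 767 in replicate 2. In Pkm, 1 of 1159 and 0 of 993 reads held both of the 167-base exons. The AMPA receptor gene Gria1 had 0 of 161 and 0 of 173 reads with both of its 115-base exons, and Gria2 had 6 of 287 and 6 of 270. In Tpm3, 0 of 308 and 0 of 282 reads held both of the 76-base exons. The 33-base and 123-base exons of Mbp were together less often than their own shares give, in 27.4% and 26.8% of reads (adjusted Fisher p 3.57e-18 and 5.99e-15).

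Other exons went together. In Bin1, a membrane-bending protein gene, the exons of 108 and 24 bases that start at 32429196 and 32429700 on mm10 chromosome 18 were both present in 136 and both absent in 40 of 177 reads in replicate 1. In replicate 2 the counts were 116 and 22 of 140. Clta, a clathrin light chain gene, had its 54-base and 36-base exons both present in 68.8% and 58.8% of reads (adjusted Fisher p 2.66e-10 and 5.55e-07). The splicing regulator Mbnl2 had its 36-base and 95-base exons both present in 56.9% and 57.0% (p 6.45e-23 and 2.09e-17 by Fisher's test), and in Mapt the pair of 87-base exons went together (p 1.82e-04 and 2.34e-04). Of 1539 pairs of variable exons in 445 genes, 513 were together and 46 apart more often than their shares give in both libraries, by Fisher's exact test adjusted over pairs, and 214 in 1 library only. None was together in one library and apart in the other. In 28 pairs, over 90% of reads held exactly 1 of the exons. Reads of one gene are not independent replicates.

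For the 10 genes that differed by at least 8-fold, a candidate explanation is the assignment of the same reads to different overlapping genes. In the annotation, 4 of the 10 overlap another gene on the same strand and 6 do not. Over the same exons and strand, whatever gene the reads were given to, the median difference was 1.70-fold. For Klhl10, Pcdhga2, Tcte1, Ccdc159 and Gm37313 the same exons differed by 1.00 to 1.59-fold, and for BC065397 by 2.13-fold in the direction of the gene's reads. The direction changed for Gm49325, Tcte1, Ccdc159 and Gm37313, which were lower in replicate 2 as genes and had log2 ratios over the same exons of 0.85 (1.80-fold, 20 and 33 reads), 0.32, 0.10 and 0.01. In the library where Klhl10, Tcte1 and Gm37313 had fewer reads, models outside known genes held 169, 138 and 36 reads over these exons. The pseudogenes Gm11223 (11.8-fold) and Mpc1-ps (10.3-fold) and Gm49450 (5 and 212 reads as a gene, 0 and 210 over its exons) were exceptions, for which other explanations stay open. Of these, Gm49450 overlaps another gene on the same strand, and its models in replicate 1 did not reach the limit of overlap with its main exons. No biological explanation was tested.

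The lower reads of myelin genes in replicate 2 were weighed against the same explanation. Over the same exons and strand the list's log2 ratio was -1.06, which argues against assignment as the cause. A difference in transcript length recovery was tested with 10000 random lists matched on expression and length: the list's median log2 ratio of -1.15, over 13 members, lay at percentile 0, which argues against length. Ttr, a marker of choroid plexus, was lower in replicate 2 by a similar amount (log2 ratio -1.14), while the other members of its list (20 and 16 reads, -0.17) did not pass. The sample-level labels name different animals for each library and the experiment-level description names the same ones, so no biological explanation was tested. A difference in the animals, in the tissue taken or between preparations of the libraries stays open. Genomic models held 6.23% of reads in replicate 1 and 7.23% in replicate 2, with median lengths of 1675 and 1255 bases. Spliced reads were 80.3% and 78.5%, while the median length of annotated transcripts was 2230 and 2272 bases. Whether these differences bear on the myelin genes was not tested.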
